A study of Mus musculus with 23 samples.

How the data were processed

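Connecting tubules and cortical collecting ducts were dissected from mouse kidneys, and RNA from 23 samples was sequenced after full-length cDNA synthesis (SMART-Seq HT) and Nextera XT library preparation. Knockout mice carried floxed Nr3c2 with an inducible, tubule-specific Cre and drank 2 mg/ml doxycycline in 5% sucrose for 2 weeks, followed by 2 weeks without it; control mice of the same genotype received no doxycycline. Per the submitters' processing notes, reads were quantified with Salmon (version listed as 0.14.10) against GRCm38.p6. The authors deposited expected counts, estimated per gene, of which 35.9% of the values are not whole numbers, and the deposited TPM, a length-scaled share of the transcripts, which add up to the same total in each library. Both tables hold 54393 genes, all of which matched a symbol and GRCm38 coordinates in the GENCODE annotation; 104 symbols belong to more than 1 gene ID. No library was left out, and no duplicated library was found among the 55 pairs within groups.

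Expected counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, the default low-count filter, 1 mean per group over all 23 libraries and quasi-likelihood F tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 25829 genes and 19 residual degrees of freedom, with a common biological coefficient of variation of 0.56. All adjusted p-values of genes come from this fit unless another tool is named. CPM values are scaled by TMM and given as mean and SD over libraries. The comparisons were KO-NK against CT-NK, CT-HK against CT-NK, KO-LK against CT-NK, KO-NK against KO-LK, KO-NK against CT-HK, the mean of the knockout against the mean of the control groups, and the difference of the 2 diet effects. Depth was 16158408 to 34154475 estimated counts per library (mean 25080000, SD 4320000).

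Gene groups were 36 lists of transport pathways, cell type markers, stress and metabolic pathways, fixed before the data were examined, each with at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with a correlation estimated per list, and with fry. The list names Bmal1, Ctgf and Cyr61 are absent from the tables, where these genes appear as Arntl, Ccn2 and Ccn1. Genes named in the text follow a rule fixed before the data were examined: the targeted gene, per comparison the 12 higher and 12 lower genes of smallest p with an absolute log2 fold change of at least 1 and a mean of at least 5 CPM in the higher group, up to 4 genes of smallest p per list, a fixed set of transport genes, and 10 for the difference of diet effects. Predicted genes were not named, and 1 gene that the rule selects is not reported here.

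Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter and a stricter one (5 CPM in 5 libraries), limma on log2(TPM + 1), a replicate block, covariates for neighbouring tubule segments and for intercalated cells, a robust fit, a fit of only the groups compared, a test against a 1.2-fold change, and leaving out each library. Added after the data were seen were a covariate for counts on olfactory and vomeronasal receptor genes, leaving out the 8 libraries above 2500 CPM on those genes, leaving out the 2 libraries richest in proximal tubule transcripts, an offset for transcript length, sample weights, and the lists for the difference of diet effects. A covariate for sex was planned only for libraries that differ in Y chromosome genes and was not run. Each comparison was repeated on 80 divisions of the libraries, the real one included. The pipeline was tested on simulated counts with known changes in the sizes of the real groups. There edgeR recovered 38% of genes raised 2-fold and 80% of genes raised 4-fold in 6 against 5 libraries. It made 4 false calls among 24276 genes. The changed genes were drawn from those above a minimum mean CPM. Simulated genes varied independently, so the false calls leave out spread shared across genes. Other divisions of the real libraries gave up to 8597 calls in CT-HK against CT-NK.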

Results

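Gene expression was measured in connecting tubule and cortical collecting duct, the aldosterone-sensitive end of the nephron, dissected by hand from kidneys of mice that carried a floxed Nr3c2 gene. Nr3c2 encodes the mineralocorticoid receptor, which aldosterone activates. A tubule-specific, doxycycline-dependent Cre system removed the floxed part in mice that drank doxycycline, and control mice of the same genotype drank sucrose water without it. The 23 libraries fell into 4 groups: control on normal potassium (CT-NK, n = 5), control on high potassium (CT-HK, n = 6), knockout on normal potassium (KO-NK, n = 6) and knockout on low potassium (KO-LK, n = 6), with 4 days on each diet. Libraries held 16158408 to 34154475 estimated counts, with group means of 25160000 (SD 3370000) in CT-NK, 27730000 (SD 4790000) in CT-HK, 22250000 (SD 3620000) in KO-NK and 25180000 (SD 4360000) in KO-LK. Each knockout comparison also compared doxycycline with no doxycycline, and the labels give a rescue diet during the washout for the knockout mice without saying whether control mice ate it. The labels number replicates per group without stating that each library came from a separate animal, so the p-values measure the spread between these libraries.

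The targeted gene was examined first. Nr3c2 (ENSMUSG00000031618, GRCm38 chromosome 8, 76899442 to 77245012, plus strand) averaged 108 ± 33.2 CPM (counts scaled to a common library size; SD, n = 5) in CT-NK and 108 ± 25.8 (n = 6) in CT-HK, against 58.8 ± 10.4 (n = 6) in KO-NK and 54.3 ± 15.6 (n = 6) in KO-LK. Per library, Nr3c2 stood at 120, 117, 152, 84.3 and 66.6 CPM in CT-NK and at 112, 145, 120, 90.0, 112 and 70.2 CPM in CT-HK. The KO-NK libraries held 48.1, 53.8, 47.7, 68.7, 63 and 71.5 CPM of Nr3c2, and the KO-LK libraries 44.5, 34.2, 44.6, 74.1, 68.4 and 59.9 CPM. CT-NK replicate 5 and CT-HK replicate 6 lay within the range of the knockout libraries. The part of Nr3c2 that was removed is not given in the labels. Counts from the rest of the gene can remain in a knockout, and counts per gene cannot tell these from counts of the intact gene.

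Nr3c2 fell by 0.88 on the log2 scale in KO-NK against CT-NK (SE 0.22, adjusted p = 0.0373), by 0.99 in KO-LK against CT-NK (SE 0.22, adjusted p = 0.0134) and by 0.88 in KO-NK against CT-HK (SE 0.21, adjusted p = 0.0112). Between the control groups the log2 fold change of Nr3c2 was 0.00 (SE 0.22), and between the knockout groups 0.12 (SE 0.21, adjusted p = 0.933). All 3 falls were also called by DESeq2, and by edgeR without CT-NK replicate 5 and CT-HK replicate 6. Leaving out 1 library ended the first call for CT-NK replicate 1 (-0.84, adjusted p = 0.0816), replicate 2 (-0.85, 0.0793), replicate 3 (-0.72, 0.117) and KO-NK replicate 1 (-0.82, 0.0749), and the KO-LK call without CT-NK replicate 3 (-0.84, 0.055). In TPM, which divide by transcript length and were not scaled by TMM, Nr3c2 averaged 40.9 ± 13.5 in CT-NK, 38.2 ± 9.67 in CT-HK, 34.9 ± 5.16 in KO-NK and 34.1 ± 8.89 in KO-LK. On log2(TPM + 1) limma called no difference (-0.17, adjusted p = 0.648; -0.23, 0.657; -0.10, 0.713). TMM factors averaged 0.966 in CT-NK, 0.887 in CT-HK, 1.085 in KO-NK and 1.102 in KO-LK. Leaving them out raises knockout values relative to control values. The 3 calls of Nr3c2 also ended with transcript length as an offset (-0.57, adjusted p = 0.161; -0.58, 0.129; -0.60, 0.0617) and without the 8 libraries richest in olfactory and vomeronasal receptor counts (-0.82, 0.21; -0.93, 0.229; -0.80, 0.0795), and the first 2 with a replicate block (-0.87, 0.101; -0.99, 0.0521).

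**Figure D1:**
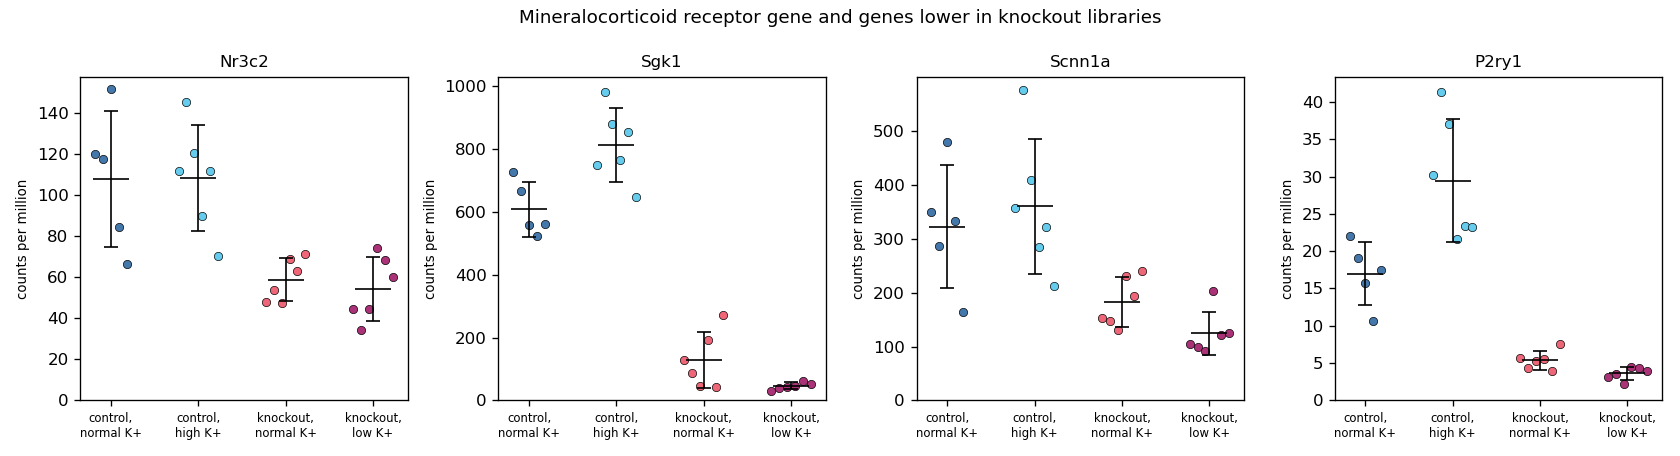
CPM of Nr3c2, Sgk1, Scnn1a and P2ry1 in each of the 23 libraries (points), with the group mean and SD (bars); axes start at 0. Sgk1 and P2ry1 lie lower in all 12 knockout libraries than in all 11 control libraries, while the groups overlap for Nr3c2 and Scnn1a.

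Knockout and control were first compared on the same diet, normal potassium (6 against 5 libraries). Sgk1, the aldosterone-induced kinase that restrains removal of the epithelial sodium channel, fell from 608 ± 86.0 to 129 ± 90.0 CPM (SD), a log2 fold change of -2.24 (SE 0.34, adjusted p = 0.000803). P2ry1, a purinergic receptor, fell from 17.0 ± 4.25 to 5.38 ± 1.27 CPM (-1.66, SE 0.23, adjusted p = 0.00038), and Gchfr, the feedback regulator of GTP cyclohydrolase, from 38.8 ± 9.78 to 13.2 ± 5.16 CPM (-1.55, SE 0.23). Atp12a, a subunit of the colonic proton-potassium pump, rose from 5.42 ± 3.58 to 34.7 ± 10.8 CPM (2.68, SE 0.43, adjusted p = 0.00152), and Nedd4l, the ubiquitin ligase that removes the sodium channel, from 223 ± 68.9 to 483 ± 109 CPM (1.12, SE 0.19, adjusted p = 0.00179).

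Of the 25 tested mineralocorticoid and corticosteroid target genes, 4 rose and 7 fell in KO-NK against CT-NK, and 5 rose and 10 fell when adjusted over the list alone. Beside Sgk1, the transcriptional regulators Tsc22d3 (-1.07, SE 0.21) and Zbtb16 (-1.70, SE 0.35) and the metallothionein Mt2 (-1.68, SE 0.28) fell. Edn1, which encodes endothelin-1, rose (1.94, SE 0.33), as did Pdk4, which inhibits pyruvate dehydrogenase (3.23, SE 0.35, adjusted p = 6.81e-05). With members moving both ways the list was not called by camera (adjusted p = 0.154, lower, with a median of -0.06 relative to all genes). Zbtb16 was no longer called when only the 2 groups entered the fit (-1.68), nor Edn1 without the 8 libraries richest in chemosensory receptor counts (1.80).

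Sodium channel subunits did not pass the test in KO-NK against CT-NK: Scnn1a had a log2 fold change of -0.82 (SE 0.26, adjusted p = 0.122), Scnn1b of 0.04 (SE 0.23) and Scnn1g of 0.74 (SE 0.21, adjusted p = 0.081). Among the 19 sodium transport genes Nedd4l rose and Sgk1 fell, and 2 rose and 4 fell adjusted over the list alone. The list was lower by camera (adjusted p = 0.0293; adjusted p = 0.604 with an estimated correlation), but not without CT-NK replicate 1 (0.298) or 3 (0.215) or KO-NK replicate 1 (0.111) or 3 (0.64). Atp12a alone was called among the 20 potassium channels and transporters, whereas Kcnj1, the secretory potassium channel, stood at 0.61 (SE 0.23, adjusted p = 0.229). Slc12a3, the thiazide-sensitive cotransporter of the neighbouring distal convoluted tubule, stood at 1.45 (SE 1.34, adjusted p = 0.812). In the WNK pathway list 1 of 16 members rose and 1 fell, and camera did not call it (adjusted p = 0.882, lower, with a median of -0.09 relative to all genes).

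Principal cell markers were higher as a group in KO-NK (camera adjusted p = 0.000659; adjusted p = 0.558 with an estimated correlation), with Krt8 at 1.54 (SE 0.27) and Krt18 at 1.41 (SE 0.26) the 2 called members of 18. Both keratins are also general markers of epithelial stress and stand on the tubule injury list. Aqp2, the water channel that marks principal cells, was not called, and its mean was lower: 2204 ± 1180 CPM in KO-NK against 3043 ± 1200 in CT-NK. Of 12 markers of beta and non-alpha intercalated cells, 3 fell and none rose, among them Spink8 (-1.53, SE 0.22; camera adjusted p = 2.85e-06; adjusted p = 0.147 with an estimated correlation). S100g, a calcium-binding protein of the connecting tubule, fell from 4474 ± 923 to 1154 ± 331 CPM (-1.95, SE 0.34, adjusted p = 0.00241). The kallikrein genes Klk1b8 (-2.16, SE 0.27) and Klk1b3 (-1.90, SE 0.31) also fell, with values that are uncertain because reads can be shared among these close paralogs.

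Immediate early and dissociation stress genes rose in KO-NK: 13 of 27 were called higher and none lower, and 21 adjusted over the list alone (camera adjusted p = 2.04e-36; adjusted p = 0.0119 with an estimated correlation, the only list of the comparison still called that way). Myc rose by 3.78 (SE 0.49), Fos by 2.00 (SE 0.38), Jun by 1.88 (SE 0.39) and Egr1 by 1.73 (SE 0.36). The unfolded-protein regulator Ddit3 rose by 1.73 (SE 0.28). Clock genes moved in both directions, with 3 of 20 higher and 3 lower: Nfil3 (3.77, SE 0.47) and Arntl (2.08, SE 0.43) rose and Dbp (-1.71, SE 0.29) and Ciart (-2.22, SE 0.39) fell. Camera did not call the clock list (adjusted p = 0.873, higher, against a median of -0.19 relative to all genes). Arntl was no longer called when only the 2 groups entered the fit (2.08).

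**Figure D2:**
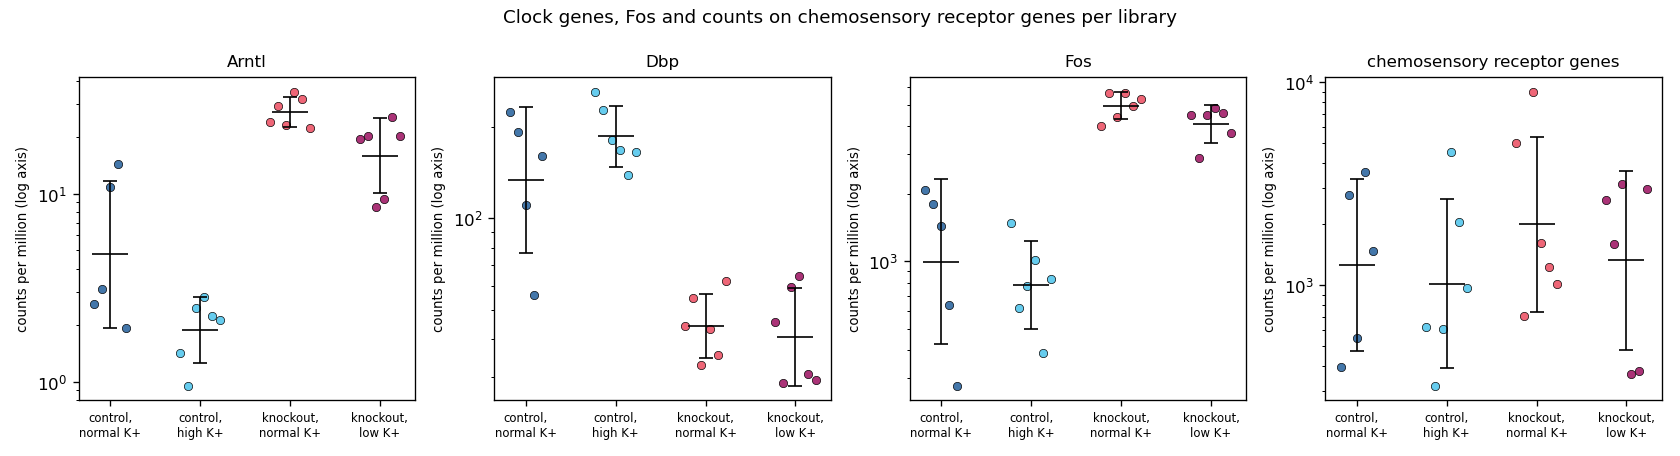
CPM of Arntl, Dbp, Fos and the summed olfactory and vomeronasal receptor genes in each of the 23 libraries (points, log axis), with geometric mean and SD (bars). Fos lies higher in all 12 knockout libraries than in all 11 control libraries. Arntl lies higher and Dbp lower on average in the knockout groups, with some libraries of the genotypes overlapping. The receptor sums overlap, from 320 to 8979 CPM.

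Genes of oxidative phosphorylation encoded in the nucleus fell: 20 of 51 were called lower, none higher, and 47 adjusted over the list alone, with a median of -0.80 relative to all genes (camera adjusted p = 4.03e-61; adjusted p = 0.0853 with an estimated correlation). Sdhc of complex II fell from 231 ± 20.1 to 121 ± 24.0 CPM (-0.93, SE 0.16) and Ndufa1 of complex I from 442 ± 65.9 to 220 ± 57.6 CPM (-1.01, SE 0.18). All 15 mitochondrially encoded genes had negative values and 1 was called (camera adjusted p = 3.89e-17; adjusted p = 0.114 with an estimated correlation). They made up 15.3 ± 3.62% of the counts in CT-NK, 15.6 ± 3.4% in CT-HK, 10.9 ± 1.56% in KO-NK and 10.4 ± 2.07% in KO-LK. Cell cycle genes were lower as a group, with 3 of 26 called lower and 14 adjusted over the list alone (camera adjusted p = 3.1e-17; adjusted p = 0.114 with an estimated correlation).

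Markers of other cell types moved alongside these groups. All 25 proximal tubule markers had negative values in KO-NK against CT-NK, with a median of -1.65 relative to all genes, and none was called (camera adjusted p = 0.000184; adjusted p = 0.604 with an estimated correlation; 0.109 with the preset one without CT-NK replicate 5). Slc34a1, the proximal tubule phosphate transporter, averaged 938 ± 1110 CPM in CT-NK and 288 ± 181 in KO-NK, with 2782 CPM in CT-NK replicate 5. Fibroblast, pericyte and smooth muscle markers were lower (1 of 16 called; camera adjusted p = 0.000659; adjusted p = 0.469 with an estimated correlation; 0.225 with the preset one without CT-NK replicate 5), with Dcn at -2.15 (SE 0.32). Macrophage and leukocyte markers had no called member, and their camera call (adjusted p = 0.0152; adjusted p = 0.604 with an estimated correlation) ended without CT-NK replicate 3 (0.481), 4 (0.0591) or 5 (0.0627) or KO-NK replicate 3 (0.112) or 5 (0.166). Alpha intercalated, distal convoluted tubule, thick ascending limb, endothelial and podocyte markers were not called as groups.

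In all, 439 of 25829 tested genes differed between KO-NK and CT-NK at an adjusted p of 0.05, 242 higher and 197 lower, of which 227 by 2-fold or more. The median log2 fold change of all genes was 0.15, and list medians in the text are given relative to that of all genes in each comparison. Without CT-NK replicate 5 the count was 233 and without KO-NK replicate 3 it was 919. Of all libraries KO-NK replicate 3 had the lowest depth (16158408 estimated counts) and the lowest share of protein-coding counts (88.8%). It also had the highest olfactory and vomeronasal receptor counts (8979 CPM). Whether these properties account for the change in count was not tested. Under limma on log2(TPM + 1), which leaves out the TMM scaling, 95.6% of 3041 called genes were higher, against 55.1% of the 439. In camera 18 of 36 lists were called, 1 with an estimated correlation, and fry called 8.

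Knockout on low potassium was compared with control on normal potassium, to ask which differences from control were present when the knockout mice ate little potassium (6 against 5 libraries). Sgk1 averaged 46.1 ± 11 CPM in KO-LK and was lower than in CT-NK (-3.72, SE 0.36, adjusted p = 4.2e-06), and Scnn1a, the alpha subunit of the sodium channel, fell from 323 ± 114 to 124 ± 40.4 CPM (-1.38, SE 0.26, adjusted p = 0.00511). Gchfr (-2.46, SE 0.24), P2ry1 (-2.23, SE 0.23) and Klf15, a glucocorticoid-responsive transcription factor (-1.47, SE 0.21), were also lower. Rasl11b, a small GTPase, rose from 11.4 ± 4.09 to 44.6 ± 5.99 CPM (1.97, SE 0.22, adjusted p = 3.25e-05), together with the protease gene Adamts16 (1.99, SE 0.24), the cadherin gene Cdh3 (2.19, SE 0.28) and Stc1 (2.55, SE 0.35), which encodes stanniocalcin.

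Of the 25 mineralocorticoid and corticosteroid targets, 10 fell and 4 rose in KO-LK against CT-NK, and 10 and 6 adjusted over the list alone. Fkbp5 (-1.37, SE 0.27; not called with proximal tubule and thick ascending limb scores as covariates, -1.05), Usp2 (-1.02, SE 0.20), Zbtb16 (-1.80, SE 0.35), Mt1 (-1.60, SE 0.25) and Mt2 (-1.80, SE 0.28) were lower, and Edn1 (2.01, SE 0.33) higher. The list was called lower by camera (adjusted p = 0.00147; adjusted p = 0.306 with an estimated correlation; 0.0568 with the preset one without CT-NK replicate 3). Among sodium transport genes Nedd4l rose (0.98, SE 0.19) and Scnn1a, Sgk1 and Usp2 fell, while Scnn1b stood at 0.01 and Scnn1g at 0.61 (SE 0.21, adjusted p = 0.159). Kcnj1 stood at 0.61 (SE 0.23, adjusted p = 0.204), and Atp12a rose by 2.58 (SE 0.43). The calcium-binding proteins Calb1 (-1.74, SE 0.32) and S100g (-1.60, SE 0.34) fell. Scnn1a, Nedd4l, Usp2, Mt1, Mt2, Edn1, Atp12a, Calb1 and S100g lost the call without the 8 libraries richest in chemosensory receptor counts, which left 3 libraries in each group, and Atp12a also with the covariates for proximal tubule and thick ascending limb (2.07).

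Several groups called in KO-NK were also called in KO-LK, but both were compared with the same CT-NK libraries, so lists called in both are not independent. Immediate early genes were higher (8 of 27 called, 18 adjusted over the list alone; camera adjusted p = 6.74e-24; adjusted p = 0.0599 with an estimated correlation), including Myc (3.62, SE 0.49), Fos (1.74, SE 0.38) and Ccn1 (2.43, SE 0.45). Nuclear oxidative phosphorylation genes were lower (32 of 51 called, 50 adjusted over the list alone; camera adjusted p = 8.53e-68; adjusted p = 0.0599 with an estimated correlation), with Sdhc at -0.99 (SE 0.16). Mitochondrially encoded genes were lower (camera adjusted p = 5.85e-17; adjusted p = 0.117 with an estimated correlation). Principal cell markers were higher (Krt8 1.82, SE 0.27; Krt18 1.66, SE 0.26; camera adjusted p = 7.66e-05; adjusted p = 0.441 with an estimated correlation), although the mean of Aqp2 was lower (1959 ± 537 CPM in KO-LK, 3043 ± 1200 in CT-NK). The tubule injury list was also higher, and its called members were the same 2 keratins (camera adjusted p = 0.000143; adjusted p = 0.117 with an estimated correlation). Dbp (-1.79, SE 0.29) and Ciart (-1.90, SE 0.39) fell and Nfil3 rose (3.22, SE 0.46). Fos, Ccn1 and Ciart were not called without the 8 libraries richest in receptor counts, nor Ciart with the covariates for proximal tubule and thick ascending limb. The cell cycle list was not called (median -0.03 relative to all genes, adjusted p = 0.545).

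Proximal tubule markers were again lower: all 25 had negative values, none was called over all genes and 24 were called adjusted over the list alone, with a median of -2.79 relative to all genes (camera adjusted p = 3.37e-11; adjusted p = 0.441 with an estimated correlation). Slc34a1 averaged 91.9 ± 49.3 CPM in KO-LK (-3.35, SE 1.11, adjusted p = 0.132). The count was 528 genes, 236 higher and 292 lower, with 257 changed by 2-fold or more, and 296 without CT-NK replicate 5. Of the called genes 44.7% were higher, against 95.6% of 4361 under limma on log2(TPM + 1) and 55.1% of 554 with transcript length as an offset. Because both comparisons used the CT-NK libraries, their 274 shared calls are not independent, and independent lists would share 4.4 (2.2 per direction). Simulated groups without effect shared 0, but such groups have hardly any calls to share, so that 0 tests nothing. Comparisons that each used a separate part of the controls shared a median of 45 (5 to 80). Fewer control libraries enter each part, so 45 and 274 are not like for like. The covariance of the 2 sets of fold changes was 0.224, against 0.194 in the simulation and a median of 0.073 with separate controls (r 0.11, -0.30 to 0.38).

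**Figure D3:**
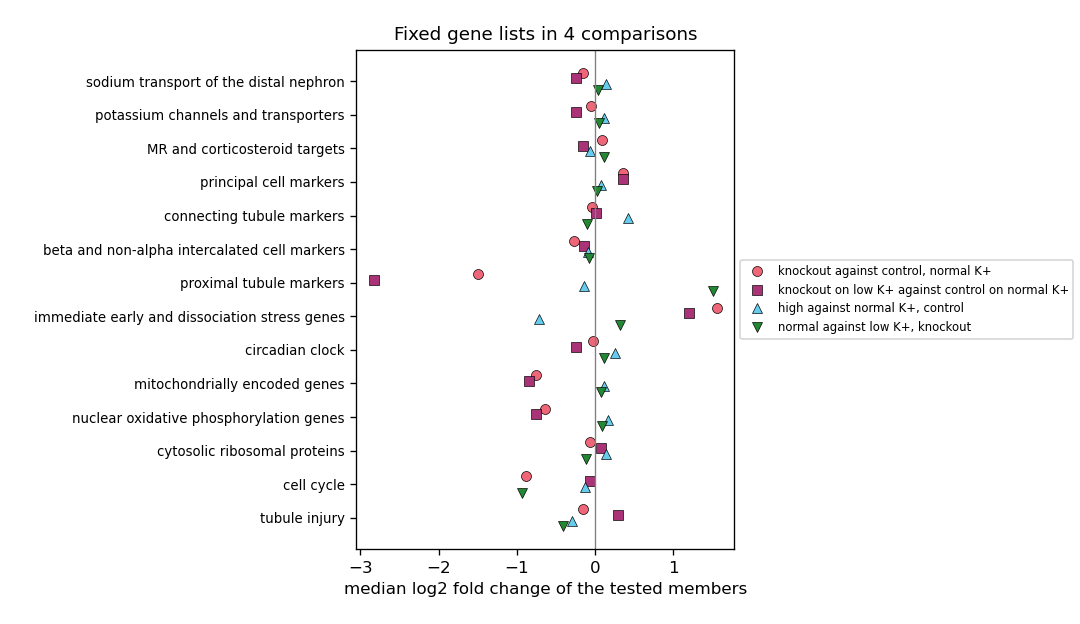
Median log2 fold change of the tested members of 14 fixed gene lists (points) in 4 comparisons; the vertical line marks 0. Immediate early genes lie to the right (1.56 and 1.2) and oxidative phosphorylation genes to the left (-0.64 and -0.76) in both knockout comparisons, and proximal tubule markers lie farthest left (-1.50 and -2.83).

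Knockout on normal potassium was also set against control on high potassium, a comparison that shares no library with the preceding one. Atp12a was 1.46 ± 0.794 CPM in CT-HK and rose by 4.57 (SE 0.45, adjusted p = 1.39e-06) in KO-NK. Rasl11a (5.06, SE 0.43), Cdkn1a, a cell cycle inhibitor (1.79, SE 0.17), and Prr5l (1.95, SE 0.17) rose. P2ry1 (-2.45, SE 0.22, adjusted p = 7.75e-07), Sgk1 (-2.66, SE 0.33), Fkbp11 (-1.80, SE 0.18) and Bdh1, an enzyme of ketone body metabolism (-2.29, SE 0.25), fell. Calb1 (-2.03, SE 0.31), S100g (-2.74, SE 0.34) and Klk1, renal kallikrein (-2.22, SE 0.40), were lower. Scnn1a was lower (-0.98, SE 0.25, adjusted p = 0.0188), but not without CT-HK replicate 2 (-0.79), on TPM (-0.33), with the transcript length offset (-0.84) or without the libraries richest in receptor counts (-0.88).

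Against CT-HK, 24 of 27 immediate early genes were higher in KO-NK and none lower (25 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.48e-50; adjusted p = 0.00193 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower in 48 of 51 cases, and all 51 adjusted over the list alone (camera adjusted p = 1.05e-64; adjusted p = 0.0699 with an estimated correlation). The clock list had 6 members higher and 8 lower of 20, with Arntl at 3.78 (SE 0.44) and Dbp at -2.07 (SE 0.28). Of the corticosteroid targets 6 rose and 10 fell, and 5 of 19 sodium transport genes fell and 2 rose (camera adjusted p = 0.000999; adjusted p = 0.429 with an estimated correlation; 0.0796 with the preset one without KO-NK replicate 3). Connecting tubule markers were lower (4 of 13 called; camera adjusted p = 2.16e-05; adjusted p = 0.416 with an estimated correlation). Proximal tubule markers had a median of -1.53 relative to all genes and were not called (camera adjusted p = 0.858), but CT-HK replicate 6 set that sign: without it the list was higher in KO-NK (camera adjusted p = 2.44e-08). Slc34a1 stood at 4420 CPM in that library, at 27.9 to 137 CPM in the other CT-HK libraries and at 104 to 538 CPM in KO-NK. The median log2 fold change of all genes was 0.21. The count was 1494 genes, 636 higher and 858 lower, and 42.6% were higher, against 97.0% of 5505 under limma on log2(TPM + 1).

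Across these 2 comparisons on separate libraries, KO-NK against CT-HK and KO-LK against CT-NK, 372 genes were called in the same direction. Of these, 139 were higher and 233 lower, with 0 in opposite directions, where independent lists would share 5.8 and 9.7. In both comparisons the knockout mice also ate less potassium than the controls and had drunk doxycycline. The shared genes therefore cannot be credited to the loss of the receptor alone. Of these shared genes 37.4% were higher. The share was 97.1% of 3031 under limma on log2(TPM + 1) and 48.5% of 369 with the transcript length offset. Their balance of directions thus depended on the processing. The limma fit changed the unit and the test as well as the scaling, so the part of the scaling was not tested. Across genes, which are not independent replicates, the fold changes correlated with r = 0.31 and rho = 0.17. The shared count was 229 without CT-NK replicate 5 and 805 without KO-NK replicate 3.

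The mean of both knockout groups was compared with the mean of both control groups (12 against 11 libraries), in which the diets of the genotypes differ. Here Scnn1a (-1.18, SE 0.18, adjusted p = 9.28e-05), Sgk1 (-3.19, SE 0.24), Calb1 (-1.89, SE 0.22), Klk1 (-1.81, SE 0.29) and Kcne1, a potassium channel subunit (-0.77, SE 0.14), fell. Nedd4l rose by 1.09 (SE 0.13), Edn1 by 2.13 (SE 0.23) and Scnn1g by 0.49 (SE 0.15, adjusted p = 0.0309), and Scnn1b stood at -0.03 (SE 0.16). Of the lists, immediate early genes (23 of 27 higher; adjusted p = 0.00294 with an estimated correlation) and nuclear oxidative phosphorylation genes (50 of 51 lower; adjusted p = 0.0215 with an estimated correlation) were called with either correlation. Proximal tubule markers had 8 of 25 members lower and 24 adjusted over the list alone (camera adjusted p = 0.000248; adjusted p = 0.686 with an estimated correlation; 0.081 with the preset one without CT-HK replicate 6). The count was 2721 genes, 1207 higher and 1514 lower, and 44.4% were higher, against 95.9% of 8161 under limma on log2(TPM + 1). Kcne1 was not called in that limma fit (-0.34).

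The effect of dietary potassium in control mice was measured by CT-HK against CT-NK (6 against 5 libraries). No single gene passed the threshold. Atp12a, the colonic proton-potassium pump, had a log2 fold change of -1.89 (SE 0.42, adjusted p = 0.497). Sgk1 stood at 0.42 (SE 0.33), Kcnj1 at 0.59 (SE 0.23), Scnn1g at 0.37 (SE 0.21), Calb1 at 0.79 (SE 0.32) and S100g at 0.79 (SE 0.34). As groups, distal convoluted tubule markers (median 0.64, 3 of 17 higher adjusted over the list alone; camera adjusted p = 4.07e-10; adjusted p = 0.148 with an estimated correlation), connecting tubule markers (median 0.42; camera adjusted p = 5.65e-06; adjusted p = 0.408 with an estimated correlation) and calcium and magnesium transport genes (median 0.43; camera adjusted p = 8.85e-06; adjusted p = 0.239 with an estimated correlation) were higher on high potassium. Immediate early genes were lower (median -0.71, 3 of 27 adjusted over the list alone; camera adjusted p = 1.25e-13; adjusted p = 0.175 with an estimated correlation). Camera called 16 lists in this comparison and fry 0. As many lists were called in 40 of 80 divisions of the libraries, so these group calls can arise by chance.

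Thick ascending limb markers were higher in CT-HK (median 0.59, 13 of 14 positive; camera adjusted p = 0.00574; adjusted p = 0.553 with an estimated correlation), but not without CT-HK replicate 3 (0.109) or 5 (0.104). Fibroblast, pericyte and smooth muscle markers were lower (median -0.96; camera adjusted p = 0.000285; adjusted p = 0.495 with an estimated correlation; 0.498 with the preset one without CT-NK replicate 5). Proximal tubule markers were lower in CT-HK (camera adjusted p = 8.85e-06; adjusted p = 0.735 with an estimated correlation; 0.212 with the preset one without CT-NK replicate 5), and the 6 Y chromosome and Xist genes had a median of 0.26 (camera adjusted p = 0.000849; adjusted p = 0.0461 with an estimated correlation), the only list of this comparison called with either correlation. By edgeR 0 genes were called between CT-HK and CT-NK, with 927 at an unadjusted p under 0.05 where 1291 are expected by chance, while DESeq2 called 20, limma on log2(TPM + 1) 0 and limma with sample weights 0. Without CT-HK replicate 6 the edgeR count was 169, and 1 without CT-NK replicate 5.

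Within the knockout, normal potassium was set against low potassium (6 against 6 libraries). Cell cycle genes were lower on normal potassium: all 26 had negative values and 15 passed adjusted over the list alone, with a median of -1.07 relative to all genes (camera adjusted p = 2.61e-30; adjusted p = 0.0417 with an estimated correlation). Top2a, a topoisomerase of dividing cells, averaged 5.03 ± 2.46 CPM in KO-NK and 12.2 ± 7.49 in KO-LK (-1.28, SE 0.37, adjusted p = 0.928), against 8.93 ± 2.14 in CT-NK. Interferon response genes (camera adjusted p = 2.78e-15; adjusted p = 0.143 with an estimated correlation), macrophage markers (camera adjusted p = 6.14e-11; adjusted p = 0.24 with an estimated correlation) and tubule injury genes (camera adjusted p = 4.47e-07; adjusted p = 0.0702 with an estimated correlation) were lower as groups, and proximal tubule markers higher (camera adjusted p = 6.43e-07; adjusted p = 0.776 with an estimated correlation). The corticosteroid targets were higher (2 of 25 adjusted over the list alone; camera adjusted p = 0.00291; adjusted p = 0.493 with an estimated correlation), though not without KO-NK replicate 6 (0.0657) or KO-LK replicate 6 (0.0947).

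No single gene passed the threshold between the knockout diets. Ddit3 (1.45, SE 0.26, adjusted p = 0.191), Pdk4 (1.52, SE 0.30, 0.191) and Sgk1 (1.48, SE 0.32, 0.244) had positive values on normal potassium, and Scnn1a stood at 0.56 (SE 0.25, 0.928). By edgeR 0 genes were called, with 732 at an unadjusted p under 0.05 where 1291 are expected by chance, while DESeq2 called 25, limma on log2(TPM + 1) 1 and limma with sample weights 8. The edgeR count was 3 without KO-LK replicate 1 and 1 without KO-LK replicate 2. The median log2 fold change of all genes was 0.13. The number of called lists was 10, and 18 without KO-NK replicate 3 or 6 without KO-LK replicate 6. Fry called 0 lists, and 74 of 80 divisions of the libraries had as many camera calls, so the group calls can arise by chance.

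Whether more potassium acted differently in control and knockout mice was tested as the difference of both diet effects, although the steps differ (normal to high, low to normal). The smallest p-values belonged to Sertad1 (-1.81, SE 0.35, adjusted p = 0.386) and Ddit3 (-1.87, SE 0.38, adjusted p = 0.386). By edgeR 0 genes were called, with 974 at an unadjusted p under 0.05, and DESeq2 called 19. The edgeR count was 214 without CT-HK replicate 6 and 5 without CT-NK replicate 5. Cell cycle genes differed as a group (camera adjusted p = 3.54e-09), as did distal convoluted tubule markers (3.01e-05) and immediate early genes (1.11e-12), and none of the lists was called with an estimated correlation. Of both diet comparisons 0 called genes were shared, and across genes their fold changes correlated with r = -0.15 and rho = -0.25.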

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

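Among 85 genes taken from the naming rule and a few measures of the libraries, 15 values lay far from the other libraries of their group by Dixon's test (356 groups of libraries examined). Chance gives such a value in about 1 in 20 groups, or 18 of 356, so the number of these values is no more than chance gives, and no explanation was tested.

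In control libraries, Slc34a1 stood at 4420 CPM in CT-HK replicate 6 (others 27.9 to 137), Ciart at 6.98 in CT-HK replicate 5 (11.6 to 15.7), Pdk4 at 30.9 in CT-NK replicate 3 (7.54 to 11.3), Anxa9 at 14.6 in CT-NK replicate 3 (5.78 to 7.2), Prr5l at 14.2 in CT-NK replicate 4 (21.6 to 25.4), Wnk1 at 144 in CT-NK replicate 4 (227 to 264) and Wnk4 at 257 in CT-NK replicate 1 (82.4 to 113).

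In knockout libraries on normal potassium, Bcat2 stood at 110 CPM (others 173 to 211), Sdhc at 77.2 (121 to 148) and Slc26a4 at 591 (956 to 1270) in KO-NK replicate 3. Jun stood at 1450 (735 to 815) and Egr1 at 3070 (1920 to 2240) in KO-NK replicate 2, and Edn1 at 4.13 in KO-NK replicate 5 (7.84 to 11.1). On low potassium, Fkbp11 stood at 4.86 in KO-LK replicate 3 (7.91 to 9.18) and Sertad1 at 18.5 in KO-LK replicate 2 (28.8 to 37.3).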

How the results depend on the processing

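The alternatives with the receptor-gene covariate, without the 8 libraries richest in receptor counts, without CT-NK replicate 5 and CT-HK replicate 6, with a transcript length offset and with sample weights were chosen after the data were seen. Unless a construction is named, the cause was not tested. Counts of genes below are in the order KO-NK against CT-NK (439), KO-LK against CT-NK (528) and KO-NK against CT-HK (1494), then the genes shared by the last 2 (372).

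DESeq2 called 1169, 1372, 2630 and 851, with 20 genes for CT-HK against CT-NK, 25 between the knockout diets and 19 for the diet difference. In the simulated counts DESeq2 made 31 false calls in KO-NK against CT-NK, where edgeR made 4. DESeq2 also recovered more of the genes raised 2-fold there (54% against 38%). In CT-HK against CT-NK, where nothing was changed, DESeq2 made 5 calls and edgeR 0. A stricter filter, which tests fewer genes, gave 2462, 2392, 3539 and 1531, with 4742 for the mean of knockout against control (2721), 1 for CT-HK against CT-NK and 10 between the knockout diets; lists called were 11 for KO-NK against CT-NK (18), 10 against CT-HK (18) and 11 for the mean (17). Without a filter the counts were 186, 224, 799 and 171, and 1692 for the mean. limma on log2(TPM + 1) called 3041, 4361, 5505 and 3031, 8161 for the mean and 1 between the knockout diets, with 8 lists for KO-LK (16) and 10 for the mean; Bpgm reversed there for the mean (0.30, adjusted p = 0.0132).

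The covariates for intercalated cells and distal convoluted tubule gave 1568, 1280, 3013 and 794, with 8 genes between the knockout diets and 1 for the diet difference. Those for proximal tubule and thick ascending limb gave 280 and 153, with 134 shared. The receptor-gene covariate gave 2047, 2197, 2818 and 1198, with 5094 for the mean and 10 (KO-NK against CT-NK) and 9 (against CT-HK) lists; all 439 and 528 genes of the first 2 comparisons were among its calls. Without the 8 libraries richest in receptor counts there were 279 and 191 calls, of which 211 and 172 were among the 439 and 528, with 170 shared; fewer libraries enter there. Without CT-NK replicate 5 and CT-HK replicate 6 there were 257, with 2 for CT-HK against CT-NK and 46 for the diet difference. Sample weights gave 861, 1019, 3992 and 669, and 8 between the knockout diets. KO-NK against CT-NK had 233 with only those groups in the fit and 199 in a test against a 1.2-fold change.

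The fall of Nr3c2 kept its direction in each alternative and lost its call in several. In the order KO-NK against CT-NK, KO-LK against CT-NK and KO-NK against CT-HK, it was -0.17 (adjusted p = 0.648), -0.23 (0.657) and -0.10 (0.713) on TPM, -0.57 (0.161), -0.58 (0.129) and -0.60 (0.0617) with the length offset, and -0.82 (0.21), -0.93 (0.229) and -0.80 (0.0795) without the 8 libraries. The first was -0.92 (0.0842) without a filter, -0.87 (0.0507) with only the groups compared and -0.53 (0.186) with sample weights. In the same order, all 3 calls were kept by DESeq2 (adjusted p = 0.00167, 0.000136 and 0.000249). They were kept with the receptor-gene covariate (0.00878, 0.000814 and 0.00724). Without CT-NK replicate 5 and CT-HK replicate 6 the values were -1.01 (0.014), -1.12 (0.005) and -0.98 (0.0035).

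With a correlation estimated per list, the lists called were 1 (KO-NK against CT-NK), 1 (CT-HK against CT-NK), 0 (KO-LK against CT-NK), 1 (between the knockout diets), 1 (KO-NK against CT-HK) and 2 (mean), against 18, 16, 16, 10, 18 and 17; fry called 8, 0, 6, 0, 9 and 9.

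Leaving out each library, the genes called ranged from 233 to 919 (KO-NK against CT-NK), 0 to 169 (CT-HK against CT-NK), 296 to 736 (KO-LK against CT-NK), 0 to 3 (knockout diets), 1058 to 1929 (KO-NK against CT-HK), 2041 to 3742 (mean), 0 to 214 (diet difference), 229 to 805 (shared, genotype) and 0 to 0 (shared, diet). The values 233, 296, 2041 and 229 came without CT-NK replicate 5, the values 919, 3742 and 805 without KO-NK replicate 3, and the values 169 and 214 without CT-HK replicate 6. Nr3c2 ranged from -1.01 to -0.72, -0.13 to 0.16, -1.12 to -0.84, -0.01 to 0.17 and -0.98 to -0.73 in the first 5 comparisons, and the lists from 13 to 21, 14 to 21, 13 to 21, 6 to 18, 14 to 20 and 16 to 20 in the first 6.

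Replicate numbers did not pair the libraries by expression over all genes. Of 33 pairs of equal number, 10 had a correlation above 0.1 (range -0.70 to 0.71, median -0.15). Of 23 libraries, 0 lay closest to their own number. The spread that follows the receptor counts was not taken out first, so a weaker pairing beneath it is not excluded. With a replicate block Nr3c2 was -0.87 (adjusted p = 0.101) in KO-NK and -0.99 (0.0521) in KO-LK against CT-NK. The planned covariate for sex was not run, since the Y chromosome genes gave no library of another sex. Size factors of DESeq2 in edgeR left 889 of 915 named values as they were and moved 26 past the threshold, and leaving out each library left 11432 the same, with 168 gained and 291 lost calls. What depth limits was not separated from the spread between libraries. The simulation of groups of 6 and 5 took depth and each gene's spread from the real libraries, without spread shared across genes. In it edgeR recovered 46% of genes lowered to 0.5 and 60% of those lowered to 0.25.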

Other observations

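Vmn1r32, a vomeronasal receptor gene chosen after its values were seen, had 20 to 102 counts in each knockout library and 0 to 3 in each control library (KO-LK against CT-NK 5.44, SE 0.71, adjusted p = 0.000188; DESeq2 made no call). Aqp2, the vasopressin-regulated water channel, stood at -0.70 (SE 0.23, adjusted p = 0.0521) in the mean of knockout against control. Notch pathway genes were higher in KO-LK against CT-NK, with 2 of 17 called (camera adjusted p = 0.000375; adjusted p = 0.117 with an estimated correlation).

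The tests of the clock genes, of the heat shock genes, of the receptor counts and of the length of Nr3c2, and the divisions of the libraries for the gene counts of KO-NK against CT-NK, CT-HK against CT-NK, KO-LK against CT-NK and between the knockout diets and for the list counts of the same 4 comparisons, were chosen after the results were seen; the other divisions were planned before.

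The clock genes differed between knockout and control libraries, and time of collection is not given in the labels. Of 12 members of the opposed clock arms, 10 were called in the directions of a shift in phase, while Nr1d1 and Nr1d2 were not called, so another time of collection and a change in the tubule clock cannot be told apart. With the clock score as a covariate Sgk1 was still lower in KO-LK against CT-NK (-3.34, SE 0.50, adjusted p = 0.00836). It was not called in KO-NK against CT-NK (-1.82, adjusted p = 0.533) or against CT-HK (-2.06, adjusted p = 0.985). The scores of control (-5.63 to -1.78) and knockout libraries (-1.56 to 0.30) do not overlap, so the fit extrapolates and cannot decide on the clock difference as a cause. CT-NK replicates 3 and 4 scored -1.85 and -1.78 with 559 and 524 CPM of Sgk1. KO-LK replicate 4 scored -1.56 with 45.1 CPM, so libraries close in score still differed in Sgk1. The fit with the clock score called 0 genes against 439 in KO-NK against CT-NK, 10 against 528 in KO-LK against CT-NK, 0 against 1494 in KO-NK against CT-HK and 1 against 2721 for the mean. A score that separates the genotypes enlarges each SE, so the lost calls decide nothing. In KO-NK against CT-NK some folds shrank (Atp12a 2.68 to 1.38, P2ry1 -1.66 to -0.9, Fkbp5 -1.14 to -0.47 and Sgk1 -2.24 to -1.82). Others grew there (Fos 2.00 to 2.36 and Zbtb16 -1.70 to -1.97). In KO-LK against CT-NK Scnn1a (-1.38 to -1.26) and Nr3c2 (-0.99 to -0.83) moved little, and Gchfr stayed called (-2.04, SE 0.35, adjusted p = 0.0226). Nr3c2 moved from -0.88 to -0.59 in KO-NK against CT-HK. Immediate early genes might rise through stress during dissection, but heat shock genes had a median of -0.18 in the mean of knockout against control (-0.27 relative to all genes, adjusted p = 0.686 with an estimated correlation), which leaves this open.

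The first principal component held 50.8% of the variance of the 25829 tested genes, of which 781 are olfactory or vomeronasal receptor genes. It followed the counts on such receptor genes (r = 0.99, rho = 0.98, permutation p = 1e-05, the smallest possible, BH-adjusted 2e-05). Without the 2 farthest libraries r was 0.99. The component thus holds in part the receptor counts it was compared with. Those counts fell with library total (r = -0.67, rho = -0.70, permutation p = 0.00046, adjusted 0.00046; r = -0.55 without the 2 farthest). Genomic DNA is a candidate explanation: in males its X-linked receptor genes would lie near 0.5 of the autosomal ones, and the ratio was 0.63 (bootstrap 0.18 to 1.2, 10 X-linked genes, below 1 in 23 of 23 libraries), too wide to decide. Over other protein-coding genes of low mean, the ratio of X-linked to autosomal slopes on the receptor counts was 0.45 (0.36 to 0.57) for 434 X-linked genes below 0.5 CPM, but 1.25 (0.27 to 3.5) below 1 CPM and 1.1 (0.31 to 2.82) below 2 CPM, so it depends on that limit and the explanation stays open. Receptor counts were 0.54 higher on the log2 scale in knockout than control libraries (permutation p = 0.357), which leaves a genotype difference open.

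Nr3c2 fell more in counts than in TPM. The length implied by both units was lower by 0.30 on the log2 scale in the knockout (-0.30, permutation p = 1e-05, the smallest possible), with the highest knockout library at -0.02 and the lowest control library at 0.01. Only 0.28% of 11134 genes moved as far down, which argues against a shift shared by all genes as the whole cause, although the value is relative to other genes. A shared shift holds part of the gap, since the counts were scaled by TMM and the TPM were not. Mean TMM factors were 1.085 in KO-NK and 1.102 in KO-LK, against 0.966 in CT-NK and 0.887 in CT-HK. Shorter Nr3c2 transcripts, as a deletion would leave, are a candidate explanation for another part of the gap. With the length offset Nr3c2 was -0.57 in KO-NK against CT-NK, between -0.88 in counts and -0.17 on TPM. In all, 9 genes separate the genotypes in this way.

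Other divisions of the libraries were compared with the real one, 80 each. Only the real division reached its count for the genes of KO-NK against CT-NK (439; 1 division as large, highest other 132) and of KO-LK against CT-NK (528; 1, highest other 1). The same held for the mean of knockout against control (2721; 1, 412) and for the genes shared by KO-NK against CT-HK and KO-LK against CT-NK (372; 1, 0). Chance is unlikely there but not excluded, since 1 in 80 is the smallest share possible. The divisions cannot test a batch or a time of collection that follows the groups. For KO-NK against CT-HK other divisions reached the real count, so chance stays open (1494; 4, 3475). Where edgeR called 0 genes, all 80 divisions had as many by construction, so the count tests nothing: CT-HK against CT-NK (0; 80, highest other 8597), the knockout diets (0; 80, 4959), the diet difference (0; 80, 117) and the genes shared by both diet comparisons (0; 80, 0). Chance was not excluded for the lists called: 18 in KO-NK against CT-NK (33 divisions, highest other 24), 16 in CT-HK against CT-NK (40, 24), 16 in KO-LK against CT-NK (41, 23), 10 between the knockout diets (74, 27), 18 in KO-NK against CT-HK (27, 26) and 17 for the mean (30, 24). The divisions with 8597, 4959 and 3475 genes point to a structure of the samples other than the groups. Receptor counts differed in them by -2.30, -2.19 and -1.89 on the log2 scale, and in KO-NK against CT-HK the 3 divisions above the real count (3475, 3184 and 2145 genes) had the 3 most negative differences (-1.89, -1.97 and -1.87). In other comparisons a difference of 2.30 in KO-LK against CT-NK, of 2.01 in KO-NK against CT-NK and of -2.32 in the diet difference went with 0 genes by edgeR, and 1 of 0.25 in CT-HK against CT-NK with 637, so the part of the receptor counts in this structure stays open.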
